A study of Drosophila melanogaster with 3 samples.

How the data were processed

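The samples were whole fruit fly embryos of mixed sex, collected 0 to 24 hours after egg laying, from a transgenic line carrying CG18599 fused at its C-terminal end to green fluorescent protein (GFP). Per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, and 3 biological replicates formed 1 group. No control sample was analysed here, so no value below has a background from untagged or input chromatin beside it. With 1 group, every comparison is between places in the genome or between lists, not between conditions.

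The authors deposited peak lists on 2 genome builds, dm6 and dm3, per the labels. Each replicate has a list of peaks and background regions, made from the reads of the replicate and of a control, per the deposited notes. A pooled list was made from the reads of the 3 replicates, with no control named for it in those notes. A further list holds the peaks kept after the irreproducible discovery rate (IDR) step, which compares the ranks of peaks between replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Each peak carries a signal value computed by the authors, on a scale not given in the sources used here. It was used only to rank peaks within a list. A further deposited column holds values that were read as the −log10 of a q-value, and it served only as an alternative ranking. Replicate and pooled lists hold 30000 entries each, which is a fixed length, so their number carries no information on enrichment. The lists give no read numbers, so the depth of each library is unknown and no counting error can be given.

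Coordinates are those of dm6 throughout, counted from 1, and nothing was converted between builds. Gene models were those of Ensembl release 115 and the sequence was the matching RefSeq assembly. The summit was the position that the deposited peak offset gives. Each summit was placed within 500 bp of a transcription start site (TSS) of a protein-coding gene, else in an exon, else in an intron, else between genes. Shares were compared by Fisher's exact test, two-sided, with 885800 random positions on the same arms and with pooled-list summits lying over 1 kb from any IDR summit. A gene was called occupied when its TSS was the nearest to an IDR summit within 10 kb. For 29 gene lists, the number of occupied members was set against 10000 random lists matched on 10 classes of the length of genome nearest to a gene's TSS. These p-values are two-sided and Benjamini-Hochberg adjusted over the 29 lists, and 0.0002 is the smallest the permutations can give. Older symbols in lists given by name were matched through the synonyms of the RefSeq gene table, and dys, in the tracheal list, stayed unmatched. Lists given as a pattern of symbols were not matched through synonyms. The Notch pattern named Dl and the Wnt pattern WntD, and neither matched a gene, so these lists were tested without them.

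Replicate support was the share of IDR peaks with a summit of a replicate peak within 250 bp, over the 8858 strongest peaks of each replicate, a length equal to that of the IDR list. For comparison, the IDR peaks were placed at random on the same arms 100 times. The frequency of 15 short motifs within 50 bp of the summits was compared with windows of equal width centred 500 bp to either side, by an exact binomial test on discordant window pairs, adjusted over the 15 motifs. Summits within 50 kb of CG18599 were counted against 10000 random windows of equal width on the same arm, one-sided. Values of the 3 replicate top lists are given as mean ± SD. Peaks are not independent replicates, so p-values over peaks or genes describe these lists and not the spread between embryos.

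The steps were tested on simulated data. With random summits, 0 of 29 gene lists were called in any of 100 simulations over 13945 genes. These runs drew 1000 random lists per test, too few for a single list to pass after adjustment. The 0 was therefore nearly fixed in advance and does not measure how often false calls arise. A list of 80 genes with 40 planted, tested with 10000 random lists, was called in 100 of 100. Most of the 29 lists are much smaller, so this does not measure how often a true excess in them would be found. The motif test, which uses each summit window against both flanks, called TAATTA in 11.3% of 1000 simulations with 2000 random positions at an unadjusted threshold of 0.05, so its p-values are too small. An exact test matched within peaks, added after the data were examined, called 5.8% in the same simulations and is given beside it where the call differs.

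The genes named were fixed by a rule written before the data were examined: the gene of the nearest TSS for the 20 strongest IDR peaks; the 10 protein-coding genes with the most IDR summits; up to 4 members with the strongest peak of each list past the threshold and up to 2 of each other list; CG18599; and every Hox gene. Tests, gene lists, motifs and other settings were fixed at the same time. The other settings were further distances, the stronger part of the IDR list, other flanks, an unmatched test, the dm3 lists and leaving out each replicate. Leaving out a replicate kept the IDR peaks that the top lists of the other 2 support, 6805, 6721 and 6916 peaks without replicate 1, 2 and 3. The IDR list itself was made from all 3, so these settings shorten the list and tighten its support, and do not isolate what 1 replicate contributes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.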

Results

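Chromatin immunoprecipitation and sequencing of GFP-tagged CG18599 in whole embryos gave 8858 IDR peaks on dm6. CG18599 (FBgn0038592) lies on the plus strand of chromosome arm 3R from 18267789 to 18271172. Its 2 coding exons translate to 475 residues with the WFQNRR sequence of a homeodomain recognition helix at residue 363. The design asks where in the embryonic genome this protein was recovered. The 3 replicates were compared with the pooled lists and with each other, and the IDR peaks with the annotation and the sequence. Peak lists give no read numbers, so the depth of each library is unknown.

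The strongest IDR peak, with a signal value of 13236 in the authors' list, lay on 2L from 480558 to 481380. It sat in an intron of ush, 1368 bp upstream of the nearest TSS, that of the zinc-finger gene cbt (FBgn0043364). The next peaks were at the promoter of Ugalt, a UDP-galactose transporter gene (X, 2703658 to 2704115, 36 bp upstream of the TSS), and in an intron of CG11050 (2L, 6612431 to 6612976). Ranks 4 and 5 fell shortly upstream of a TSS of CG14100 and of px. The GAGA factor gene Trl held rank 6, in an intron (3L, 14759274 to 14759857), and the Polycomb group gene ph-p held rank 12, 451 bp upstream of a TSS of the gene (X, 2137104 to 2137615). The prohormone convertase gene amon, CG4004, the kinase gene Lk6, the glycolytic gene Gapdh2 and CG32772 held ranks 7 to 11. The kinase gene Tlk, Tina-1, CG9663, the mitochondrial ribosomal protein gene mRpL41, PNPase, the RNA-binding protein gene larp, CenG1A and the chromatin protein gene Chro completed the 20 strongest. Each of these 20 peaks stood among the first 25 of replicate 1, the first 24 of replicate 2 and the first 26 of replicate 3. Of the 100 strongest peaks, 62 lay within 500 bp of a TSS, 27 in introns and 11 between genes.

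IDR peaks covered the large chromosome arms at similar density and were sparse on chromosome 4. There were 71.1 peaks per Mb on 2L, 69.0 on X, 67.6 on 3L, 65.1 on 3R and 61.8 on 2R, against 8.90 on chromosome 4, where 12 peaks were found and 89.2 were expected by length. The pooled list, which includes background regions, held 27 of its 30000 entries on chromosome 4. The sparsity there is therefore not particular to IDR peaks and does not show that the protein avoided this chromosome. Peaks were not spread by arm length (chi-square 86.9, 5 degrees of freedom, p = 2.98e-17), nor were they without chromosome 4 (chi-square 19.3, 4 degrees of freedom, p = 0.000699). The median peak width was 440 bp and the median signal value 389.2. All 8858 IDR peaks were in the pooled list, and they were exactly its 8858 entries with the highest signal value.

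The replicates recovered largely the same places. Of the IDR peaks, 86.7% ± 1.40 (SD, n = 3) had a summit of the replicate's top list within 250 bp, against 3.20% for random placements. Over the whole replicate lists the share was 98.2% ± 0.352 (SD, n = 3), against 10.3% for random placements. Every replicate supported 6208 IDR peaks, or 70.1%, from its top list. Across peaks, not replicates, Spearman's rho of the signal values was 0.801 for replicates 1 and 2, 0.761 for replicates 1 and 3, and 0.765 for replicates 2 and 3. The IDR list was made from these replicates, so the shares describe spread and are not independent evidence.

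On dm3 the authors listed 8821 IDR peaks. Arm 3R held 2068 peaks on dm3 and 2087 on dm6, 3L 1896 and 1901, 2L 1665 and 1671, X 1638 and 1624, 2R 1545 and 1563, and chromosome 4 held 9 and 12. Replicate and pooled lists held 30000 entries on both builds.

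Promoter regions were the only class in which the share of IDR summits exceeded both backgrounds. Within 500 bp of a TSS lay 3196 summits, or 36.1%, against 11.5% of random positions (odds ratio 4.34, exact p = 1.59e-778) and 14.5% of the 17316 other pooled-list summits (odds ratio 3.33, p = 1.04e-335). Replicate top lists gave 36.4% ± 3.24 (SD, n = 3), with replicate 3 at 32.6%. Exons held 2.04% of summits, against 19.2% of random positions (exact p = 8.92e-547) and 4.13% of the other summits (p = 7.24e-20). Between genes lay 19.2%, against 30.1% of random positions (exact p = 2.00e-119) and 30.6% of the other summits (p = 4.55e-91). Introns held 42.7% of summits, more than the 39.3% of random positions (exact p = 4.61e-11) and less than the 50.7% of the other summits (p = 7.99e-35). The excess of introns over random positions was not kept with a TSS distance of 1000 bp (36.3% of summits in introns, exact p = 0.965) or in the stronger part of the list (40.4%, p = 0.127).

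The strongest peaks were the most promoter-bound. The share within 500 bp of a TSS was 54.7% in the strongest 10% of IDR peaks and 29.3% in the weakest 10% (Fisher's exact test, two-sided, odds ratio 2.92, p = 1.18e-27), a comparison chosen after the data were examined. Summits at promoters lay mostly upstream, with a median position of -106.5 bp relative to the TSS and 76.6% of them on the upstream side.

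**Figure D1:**
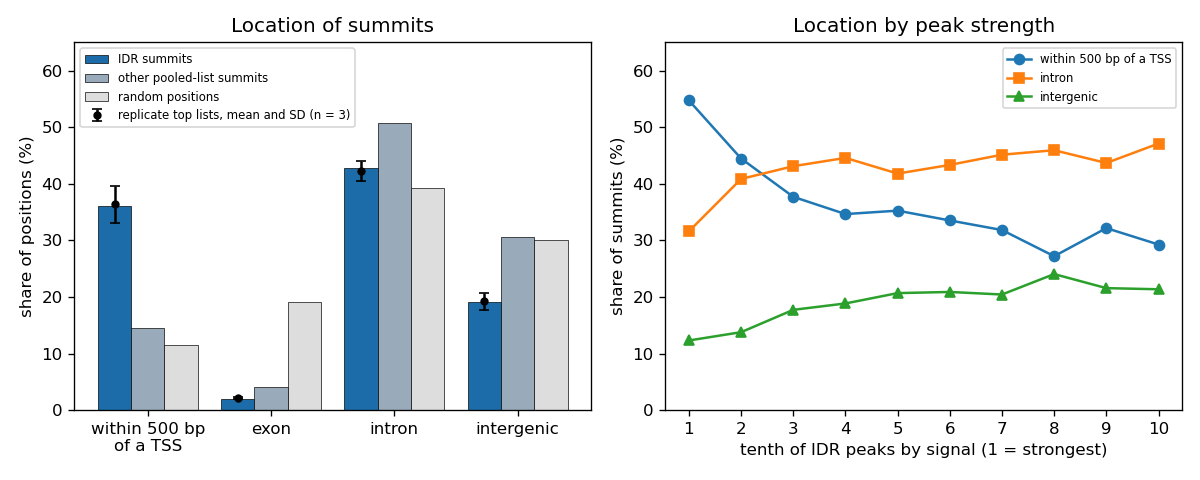
Left, share of positions (%) by location class for IDR summits, other pooled-list summits and random positions, with points and bars for the mean and SD of the 3 replicate top lists; right, share of IDR summits by signal, in 10 classes of which 1 is the strongest. The share within 500 bp of a TSS is 36.1% over all IDR summits, and 54.7% in the strongest 10% against 29.3% in the weakest 10%.

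Of 13945 protein-coding genes, 4098 (29.4%) were the nearest gene of an IDR summit within 10 kb. The 10 genes with the most summits had between 37165 and 83025 bp of genome nearest to their TSS. The zinc-finger gene shn, a mediator of Dpp signalling, had 21 summits, the RNA-binding protein gene shep and tara 19 each, and bun 18. The ecdysone-induced receptor gene Eip75B had 17, the Notch coactivator gene mam and Tlk 16 each, and the transcriptional cofactor gene ush, the muscle factor gene Mef2 and tna 14 each. Only 29 genes had 10 or more summits, and 2491 had 1. Summits were counted singly, and 625 of the 8858 lay within 250 bp of the preceding summit, so these counts can include neighbouring summits of the same region. Occupancy differed with the length of genome nearest to a gene's TSS, at 60.2% of the genes in the widest 10% and 9.82% in the narrowest 10%. Where genes shared a TSS position, it was given to 1 of them, so only 13768 of the 13945 genes could be called occupied. The remaining genes fell in the narrowest 10% and lower its share.

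Genes of cytosolic ribosomal proteins were occupied far more often than genes of matched territory. Of 92 such genes 66 were occupied, against 19.9 in matched random lists (ratio 3.31, permutation p = 0.0002, the smallest possible, adjusted p = 0.0058). The share in the replicate top lists was 70.3% ± 7.63 (SD, n = 3). In 60 of the 66 genes the strongest peak lay within 500 bp of the TSS, at a median distance of 46.0 bp over the 66, and 57 genes had 1 summit. The strongest peaks were at RpS27 (rank 148, 12 bp from the TSS), RpL7 (rank 155), RpL34b (rank 271) and RpL23A (rank 275), and 20 of the genes had a peak in the strongest 10%.

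Odorant and gustatory receptor genes, which act in chemosensory neurons, were as 1 list occupied less often than matched genes. Of 119 genes 16 were occupied, against 34.6 in matched lists (ratio 0.462, permutation p = 0.0004, adjusted p = 0.0058), and the share in the replicate top lists was 12.0% ± 0.485 (SD, n = 3). The strongest peaks assigned to them were those of Gr89a (rank 1349, 1327 bp from the TSS), Or85d (rank 2846, 6479 bp), Gr21a (rank 3632, 217 bp) and Gr93a (rank 3894, 4709 bp). All but that of Gr21a lay between genes. The size of this deficit depended on the setting: 1 gene was occupied against 21.4 (ratio 0.0467) with a distance of 1 kb, and 5 against 22.2 (ratio 0.225) in the stronger part of the IDR list. In the shorter lists of IDR peaks supported by the other 2 replicates, 9 genes were occupied without replicate 1 (ratio 0.319), 11 without replicate 2 (0.391) and 9 without replicate 3 (0.309). These were the only lists past the adjusted threshold in either direction.

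The other 27 lists did not pass it. Among housekeeping and stress genes, 12 of 48 proteasome genes were occupied against 10.7 in matched lists (adjusted permutation p = 1), with Rpn3 and Rpn11 strongest; the ratio to the matched mean was 1.12, and 0.801, 0.691 and 0.994 in the IDR peaks supported without replicate 1, 2 or 3. Of 80 mitochondrial respiratory chain genes 17 were occupied against 19.1 (adjusted permutation p = 1), with COX7C and COX7AL2 strongest. Of 16 heat shock genes 8 were occupied against 3.80 (adjusted permutation p = 0.255), with strong promoter peaks at Hsp83 (rank 100) and Hsp27 (rank 133). Of 14 eggshell genes 0 were occupied against 2.77 (adjusted permutation p = 0.422), and of 11 sperm genes 1, ProtB, against 2.39 (adjusted p = 0.896).

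Of the 8 Hox genes, 4 were occupied against 4.67 in matched lists (adjusted permutation p = 1). Antp had 2 summits (best rank 2170, 3493 bp from a TSS), Abd-B 1 (rank 1450), abd-A 1 (rank 3216) and Dfd 1 (rank 5151, 400 bp from a TSS), while lab, pb, Scr and Ubx had 0. The early patterning lists did not pass the threshold. Of 12 gap and head gap genes 3 were occupied against 6.72 (adjusted permutation p = 0.340), cnc with 13 summits and oc and ems with 1 each, while hb, Kr, kni, gt and tll had 0; ems and these 5 were named after their values were seen. The ratio to the matched mean was 0.446, and in the IDR peaks supported without replicate 1, 2 or 3 it was 0.175, 0.350 and 0.344 (adjusted permutation p = 0.0870, 0.293 and 0.266). Of 9 pair-rule genes 3 were occupied against 4.88 (adjusted permutation p = 0.798; slp2 and hry strongest), of 13 segment polarity genes 4 against 6.06 (adjusted p = 0.798; nkd and ptc), and of 14 dorsoventral genes 7 against 6.97 (adjusted p = 1; ush and sim).

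In the nervous system lists, proneural and neuroblast genes had 3 of 16 occupied against 7.44 (adjusted permutation p = 0.255; D and insc strongest), and columnar and temporal factors 3 of 11 against 5.93 (adjusted p = 0.538; grh and nub). Neuronal identity factors had 9 of 15 occupied against 7.92 (adjusted permutation p = 1), with fkh at rank 95 and zfh1 at rank 413. Neuronal differentiation genes had 7 of 14 against 6.62 (adjusted permutation p = 1), with the RNA-binding protein gene elav at rank 42 and the potassium channel gene Sh at rank 3050. Glial genes had 6 of 11 against 4.20 (adjusted permutation p = 0.848), with moody, a receptor gene of the blood-brain barrier, at rank 68, and Gli. Axon guidance genes had 14 of 21 against 10.7 (adjusted permutation p = 0.709; Fas3 and sli). Paired-class homeobox genes had 5 of 15 against 7.64 (adjusted permutation p = 0.719; PHDP and OdsH), NK-class genes 5 of 13 against 7.1 (adjusted p = 0.798; tin and NK7.1), and retinal determination genes 4 of 8 against 4.23 (adjusted p = 1; so and Optix), a ratio of 0.945 that was 0.555, 1.11 and 0.545 in the IDR peaks supported without replicate 1, 2 or 3.

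In other tissues, muscle structural genes had 5 of 15 occupied against 6.80 (adjusted permutation p = 0.896; Act57B and sls strongest) and mesoderm factors 4 of 11 against 4.51 (adjusted p = 1; bin and tin). Tracheal genes had 4 of 9 against 4.86 (adjusted permutation p = 1; trh at rank 195, and bnl), gut factors 5 of 9 against 4.69 (adjusted p = 1; fkh and bowl), and epidermis and cuticle genes 3 of 12 against 5.48 (adjusted p = 0.719; grh and ovo). Of the signalling and chromatin lists, Wnt and Frizzled genes had 6 of 10 against 5.26 (adjusted permutation p = 1; fz and fz4), Notch pathway genes 8 of 20 against 6.27 (adjusted p = 0.896; E(spl)m3-HLH and E(spl)malpha-BFM), and Polycomb and Trithorax group genes 7 of 20 against 6.68 (adjusted p = 1; Trl and ph-p). With lists this small, a difference from the matched mean that misses the threshold does not show that occupancy was equal.

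**Figure D2:**
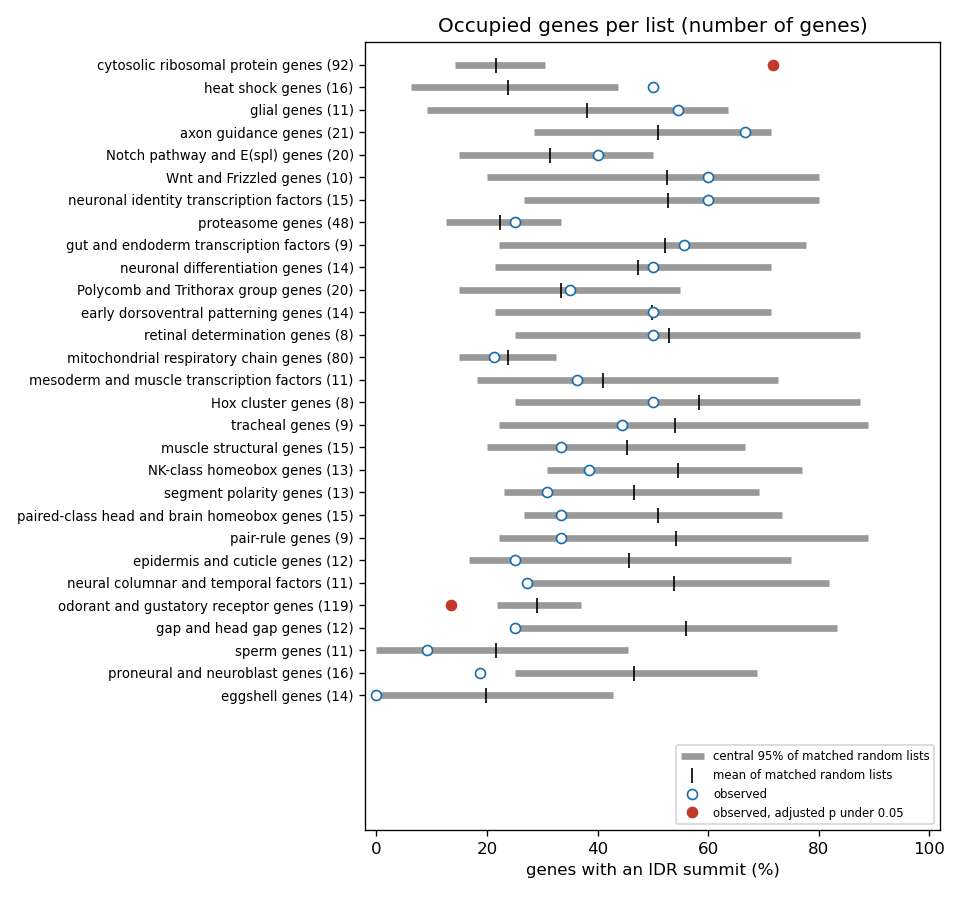
Share of genes with an IDR summit (%) for each of the 29 lists, with the number of genes in brackets; circles are the observed shares, filled where the adjusted p passed 0.05, ticks the mean and grey bars the central 95% of 10000 matched random lists. Ribosomal protein genes lie above their bar (66 of 92 genes) and receptor genes below theirs (16 of 119).

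The homeodomain core TAATTA was more frequent at summits than beside them. It was present within 50 bp of 9.04% of IDR summits and in 6.56% of flanking windows (exact binomial test, adjusted p = 1.08e-17), and the difference in the replicate top lists was 2.34 ± 0.468 percentage points (SD, n = 3). The shorter core TAAT was present at 71.8% and in 59.5% (adjusted exact p = 8.23e-129), while TAATTG did not differ, at 9.65% and 9.77% (adjusted p = 0.733). Among 2080 hexamers merged with their reverse complements, TAATTA had rank 252 by the ratio of summit to flank, and the first was ATATTA, at 18.0% and 8.35%. DNA at the summits was rich in A and T, at 64.0% ± 1.08 (SD, n = 3) in 51-bp windows of the replicate top lists, against 57.5% ± 0.0905 at 500 bp toward higher coordinates.

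Of the other motifs, TATCGATA, the element bound by DREF, was present at 0.824% of summits and in 0.214% of flanks (adjusted exact p = 8.51e-16), and CGATAG at 3.54% and 2.11% (adjusted p = 8.51e-16). GGTCACAC, the core of the element bound by M1BP, was present at 0.587% and 0.169% (adjusted exact p = 8.30e-11). TATATA was present at 10.8% and 6.04% (adjusted exact p = 9.74e-60), TGATAA at 9.66% and 6.81% (adjusted p = 1.46e-22) and TTTATG at 12.2% and 10.9% (adjusted p = 0.000327). Ratios of summit to flank were larger for hexamers richer in A and T. The median log2 ratio of hexamers was -0.523 with 2 A or T bases, -0.240 with 3, 0.520 with 5 and 0.723 with 6. The motif tests do not hold composition fixed, so an excess of A/T-rich motifs or a deficit of G/C-rich motifs may follow from it. Among peaks over 500 bp from any TSS, the differences did not pass the threshold for TATCGATA (0.0530 percentage points, adjusted exact p = 0.522), CGATAG (0.0795, adjusted p = 0.686), TTTATG (0.768, adjusted p = 0.130), TTTATTG (0.283, adjusted p = 0.460) and CAGGTAG (-0.0442, adjusted p = 0.686). CACACA (8.18% and 11.2%, adjusted exact p = 7.09e-21), GAGAG (12.0% and 13.3%, adjusted p = 0.000184) and the E-box CACGTG (0.869% and 1.24%, adjusted p = 0.00118) were less frequent at summits. TTTATTG (4.92% and 4.43%, adjusted exact p = 0.0316), CAGGTAG (0.384% and 0.570%, adjusted p = 0.0170) and CAGCTG (4.32% and 4.84%, adjusted p = 0.0239) passed this test. With the exact test matched within peaks they did not, at adjusted p = 0.0819, 0.0640 and 0.0720. With windows of 100 bp on each side, TTTATG (adjusted exact p = 0.126) and CAGCTG (adjusted p = 0.381) did not pass, and GAGAG lay above its flanks without passing (adjusted p = 0.0656). With windows of 25 bp, TTTATTG (adjusted exact p = 0.144), CAGGTAG (adjusted p = 0.302), CAGCTG (adjusted p = 0.207) and CACGTG (adjusted p = 0.267) did not pass. With flanks at 1000 bp, TTTATG (adjusted exact p = 0.174), GAGAG (adjusted p = 0.325), CAGGTAG (adjusted p = 0.314) and CAGCTG (adjusted p = 0.351) did not pass. In the IDR peaks supported without replicate 1 or replicate 2, CAGGTAG did not pass (adjusted exact p = 0.103 and 0.0983), and the difference of summit minus flank was -2.20 percentage points for GAGAG without replicate 1 and -0.803 for CAGCTG without replicate 2.

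**Figure D3:**
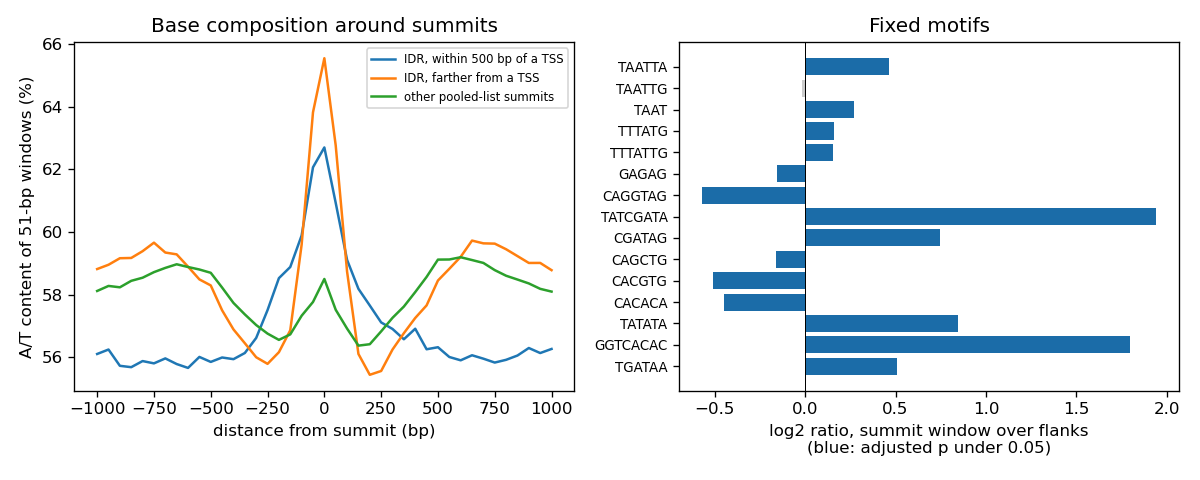
Left, mean A/T content (%) of 51-bp windows by distance from the summit (bp) for IDR summits within 500 bp of a TSS, IDR summits farther away and other pooled-list summits; right, log2 ratio of the share of summit windows with each of the 15 motifs to the share of flanking windows. A/T content peaks at the summit in both IDR classes, at 62.7% near a TSS and 65.5% farther away, and 9 motifs lie above 0 and 5 below 0 with adjusted p under 0.05.

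CG18599 was the nearest gene to 2 IDR summits, both between genes, at 18264128 (3R, peak from 18263908 to 18264347, rank 6072) and 18265520 (peak from 18265300 to 18265739, rank 8337). They lay 3661 and 2269 bp upstream of its TSS. Within 50 kb of the gene there were 15 IDR summits, the best at rank 384, against 6.78 in random windows of 3R (permutation test, one-sided, p = 0.0808). In the pooled list there were 49 summits against 23.5 (permutation p = 0.0268). Replicate lists had 50, 51 and 47 summits there, with permutation p of 0.0261, 0.0215 and 0.0292 for replicates 1, 2 and 3. Each list of IDR peaks supported by 2 replicates had 13 summits there, which passed the threshold without replicate 2 (permutation p = 0.0481) and not without replicate 1 (p = 0.0562) or replicate 3 (p = 0.0548).

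**Figure D4:**
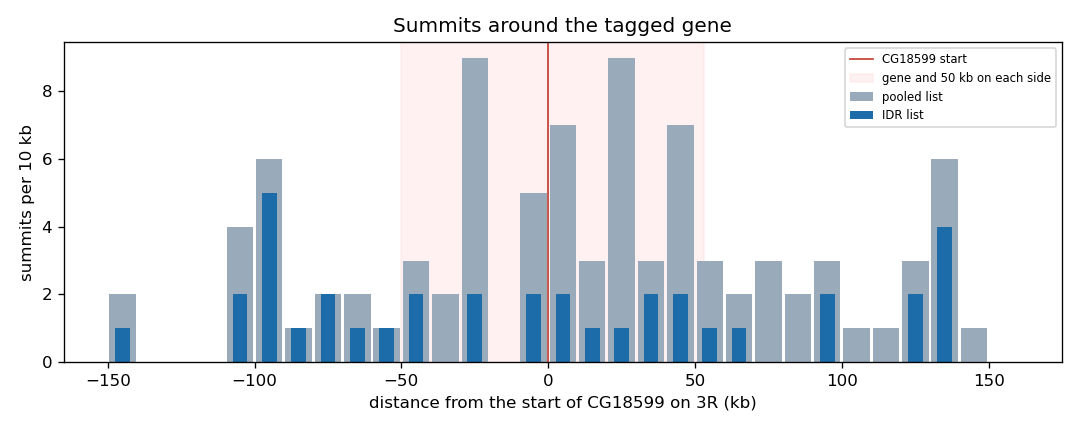
Summits per 10 kb against distance from the start of CG18599 on 3R (kb) for the pooled list (wide bars) and the IDR list (narrow bars); the shaded band is the gene with 50 kb on each side. The band holds 49 pooled-list summits and 15 IDR summits.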

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

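Entries outside the chromosome arms compared above were present in the dm3 lists. The scaffold of X heterochromatin in that build held 4 entries in the pooled list, 7 in replicate 2 and 4 in replicate 3, above the 3 that a count of 0 allows, against 3 in replicate 1 and 0 in the IDR list. These lists have a fixed length and include background regions, so the entries do not show peaks there, and the replicates were not tested against each other. No explanation was tested.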

How the results depend on the processing

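Of 533 values recomputed for 62 results, 457 kept their direction and side of the threshold or stayed within the spread set for them. The excess of ribosomal protein genes and the deficit of receptor genes passed under every alternative run, and TAATTA stayed above its flanks in each. The ratio for receptor genes ranged from 0.0467 (1 kb) to 0.598 (50 kb), and the TAATTA difference was 1.45 percentage points with 25 bp and 3.91 in the stronger part of the list. Of the 76 exceptions, 20 were losses of a call by motifs other than TAATTA, given with their p-values in Results. Where no reason is given, the cause was not tested. The stronger part of the IDR list holds 4429 peaks by construction. Mean replicate support was 81.3% with summits within 100 bp and 98.2% over whole replicate lists, as stricter or looser matching must give. With reciprocal overlap of peaks, a different rule, it was 77.7%. Mean rho across peaks was 0.604 with the q-value column and 0.802 within 100 bp, and ranged from 0.761 to 0.801 between single replicate pairs. The intron share against random positions lost its excess with a TSS distance of 1000 bp (36.3%, now level with random positions) and in the stronger part of the list (40.4%). The unmatched Fisher test called 2 lists above, adding axon guidance genes (ratio 2.27, adjusted p = 0.00429); that test does not hold territory fixed. Motifs above their flanks numbered 5 away from promoters. Motifs below numbered 2 with 25 bp, 3 with 100 bp, 2 with flanks at 1000 bp and 3 with the test matched within peaks. GAGAG turned from below to 0.892 percentage points above its flanks with 100 bp, with adjusted exact p = 0.0656. Other changes of direction, none past the threshold before or after, were in gene lists and in TAATTG. Ratios with the unmatched test were 1.70 for Hox and for retinal genes, 1.13 for pair-rule, paired-class and muscle structural genes, 1.05 for segment polarity, 1.31 for NK-class, 1.24 for mesoderm, 1.51 for tracheal and 0.851 for proteasome genes. With 1 kb they were 0.663 for dorsoventral, 1.06 for NK-class, 0.808 for neuronal differentiation, 0.809 for Wnt and Frizzled and 0.911 for proteasome genes, and with 50 kb 0.912 for dorsoventral and 0.991 for neuronal differentiation genes. In the stronger part of the list they were 0.774 for neuronal identity, 0.922 for neuronal differentiation, 1.05 for mesoderm and 0.570 for proteasome genes. In the IDR peaks supported by 2 replicates they ranged from 0.743 to 1.01 for Hox, 0.545 to 1.11 for retinal, 0.886 to 1.24 for neuronal differentiation, 1.05 to 1.07 for mesoderm, 0.691 to 0.994 for proteasome and 0.779 to 1.06 for respiratory chain genes. The TAATTG difference was 0.0621 percentage points with 25 bp, 0.147 with flanks at 1000 bp, 0.689 in the stronger part and 0.0217 to 0.375 in peaks supported by 2 replicates. Summits within 50 kb of CG18599 passed the threshold in the pooled list (49), and 13 of the IDR summits were in each list of peaks supported by 2 replicates. Counting 1 summit per 250-bp cluster and the test matched within peaks were chosen after seeing the data. The lists give no read numbers, so whether weaker peaks differ between replicates through depth is unknown. No paired analysis was possible because the samples form 1 group.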

Other observations

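The tests of gene name families and of sequences other than the fixed motifs were chosen after the data were examined. So were the tests of proteasome and respiratory chain genes and of A/T-only hexamers over all peaks, and the comparison of windows around CG18599 with equally rich windows; the remaining tests of explanations were written before their result was seen.

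Gene families sharing a symbol prefix, 39 with at least 15 members, were set against territory-matched genes. Besides the RpL and RpS genes, which overlap the list above, no family passed the adjusted threshold above its matched mean. Ir genes, ionotropic receptors of sensory neurons, had 6 of 60 occupied against 19.6 (permutation p = 0.0002, the smallest possible, adjusted p = 0.00156), and Or genes 6 of 59 against 19.0 (adjusted p = 0.00156). Gr genes, the gustatory receptors, did not pass by themselves, with 10 of 60 occupied against 15.6 (adjusted permutation p = 0.348). Cuticle protein genes of the Cpr family had 8 of 70 against 18.2 (adjusted permutation p = 0.0263), Osi genes 1 of 25 against 7.74 (adjusted p = 0.0143) and seminal fluid Sfp genes 1 of 28 against 7.32 (adjusted p = 0.0234). Histone genes, which include near-identical copies and are uncertain for that reason, had 1 occupied member against 14.3 (adjusted permutation p = 0.00156). Genes of mitochondrial ribosomal proteins were near their matched means, with 6 of 47 mRpL genes against 8.09 (adjusted permutation p = 0.828) and 6 of 26 mRpS genes against 4.58 (adjusted p = 0.848).

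A sequence outside the fixed motifs had the highest ratio among octamers present at 0.5% or more of summits. CACTGAGA lay within 50 bp of 1.43% of IDR summits and in 0.282% of flanking windows (exact binomial test, unadjusted p = 2.69e-34), and in the replicate top lists at 1.36% ± 0.163 and 0.286% ± 0.0568 (SD, n = 3). Of the 10 leading octamers, 7 held CACTG or its reverse complement. Some of them overlap, as CACTGAGA and ACACTGAG do, so 1 site can count in several and the 7 are not separate evidence. CACTG was present at 21.7% of IDR summits and in 16.2% of flanks (exact binomial test, unadjusted p = 5.35e-40), but in the strongest 10% it lay below its flanks, at 14.0% and 17.2% (unadjusted p = 0.0104). Over 500 bp from a TSS CACTGAGA was present at 1.93% of summits and in 0.318% of their flanks, within 500 bp of a TSS at 0.563% and 0.219% (exact binomial test, unadjusted p = 0.00260), and in the strongest 10% at 0.339% and 0.395%; the difference between these sets was not tested. The 127 sites within 50 bp of IDR summits had 127 distinct 32-bp surroundings. Sites within 250 bp of an IDR summit were more numerous, 346 followed by any base and AAA and 231 others. The octamer was therefore not confined to the summit window, and its excess over flanks at 500 bp does not place it at the summit. At 87 of the 127 sites (68.5%) the bases AAA followed after a gap of 1 base, against 29.8% of the 4203 other sites on the arms. Those 4203 include sites between 50 and 250 bp from an IDR summit, so they are not a set away from the peaks. Of all sites with AAA, 25.9% lay within 250 bp of an IDR summit, against 7.72% of sites without it. Both the octamer and the AAA were read from the same peaks that these counts use, so the p-values of the octamer and of CACTG overstate the evidence and no p-value is given for the AAA.

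Occupancy of ribosomal protein genes, 66 of 92 against 19.9 in matched lists, was weighed against 3 technical explanations. Recovery of housekeeping promoters as a class was set against proteasome and respiratory chain genes, of which 29 of 128 were occupied against 29.7 in matched lists. This argues against a like excess in these families. They were chosen after the data were examined, and their symbols take in paralogs such as Rpt3R and COX7AL2. They cannot stand for all housekeeping promoters, so that explanation stays open for the class. Reads shared between paralogs are argued against by the 74 ribosomal protein genes without a lettered sister gene, of which 54 were occupied against 16.4. The A/T content of promoters is argued against because the 66 genes exceeded 36, the upper end of the central range of lists matched on the 150 bp upstream of the TSS. High transcription or open chromatin at these genes, recovered without binding by CG18599, stays open, since neither expression values nor a control sample were analysed here.

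The excess of TAATTA at summits may follow from their A/T-rich DNA. Of 36 hexamers made of A and T alone, 32 had a larger ratio of summit to flank than TAATTA, whose log2 ratio was 0.46 against a median of 0.72. Binding of a homeodomain to TAATTA at the strongest peaks was taken to predict that TAATTA leads these hexamers there. In the strongest 10%, 27 of the 36 had a larger ratio. TAATTA was present there at 11.4% of summits and in 5.48% of flanks, a log2 ratio of 1.05 against a median of 1.22. This ranking cannot decide, because A/T-only hexamers such as ATATTA also hold the core TAAT, read on the other strand. Homeodomain binding, sites of another sequence, and recovery through other proteins stay open.

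The excess of pooled-list summits around CG18599 may come from extra copies of the locus carried by the transgene, or from a peak-rich region, and these cannot be told apart here. The window within 50 kb of the gene held 49 pooled-list summits, and the neighbouring windows of equal width held 19 and 24. Of 5272 windows elsewhere on the arms with at least 49 summits, taken every 1000 bp and lying in 89 separate regions, 8.50% had no more than 24 summits on either side, so such a local rise also occurs away from the gene. Of the 49, 34 were not IDR peaks, and the IDR list had 15 summits in the window against 13 and 9 beside it. The length of the transgene was not used here.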
